A study of Mus musculus with 24 samples.

How the data were processed

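RNA of the ipsilateral and contralateral hemispheres of 12 male C57Bl/6j mice, 8 with middle cerebral artery occlusion and 4 with sham surgery, was measured on 24 Affymetrix whole-transcript arrays, 1 per hemisphere. Per the labels' protocols, brains were perfused with saline, hemispheres were flash frozen, RNA was isolated with the mirVana Paris kit and labelled with the GeneChip WT Plus kit. The deposited values are log2 probe-set signals made by the authors with Affymetrix Expression Console, per the submitters' processing notes; its version is not given in the sources used here. The method of background correction, normalization and summarization and the genome build of the array annotation are not given in the sources used here. The log2 scale is inferred from the range of the values and the tool named, so folds rest on that inference. No coordinates are reported for the same reason of build.

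The value table held 29129 probe sets. The 6923 array controls were left out of tests, leaving 22206, and no filter on signal was applied. Of those tested, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 were unnamed here. All 19572 Entrez identifiers were found in a RefSeq gene table (assembly GRCm38.p6, used for names only), with 0 symbols differing. For gene lists, 1 probe set per gene was kept, the one with the highest mean over all arrays, giving 19505 genes, of which 55 had more than 1 probe set. In 0 pairs of arrays were the values identical. Mice are numbered as in the sample titles, and each mouse is a separate animal.

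Within-mouse comparisons (ipsilateral against contralateral in MCAO and in sham mice, and the interaction of side and surgery) used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 24 arrays and mouse as a fixed block, since both hemispheres came from 1 animal per the labels. Without the arrays that stood apart, the 2 hemispheres of a mouse correlated at 0.11 to 0.31 in their deviations from the group means, against a median of -0.04 for different mice. Between-mouse comparisons used the 12 arrays of 1 side with no block. P-values were adjusted by Benjamini-Hochberg over all probe sets of a comparison, with 0.05 as the threshold, and errors of log2 differences are standard errors unless SD is written. Mice that share a number across surgery groups are different animals and form no pair.

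The 33 gene lists covered immediate early, neuronal activity, stress, inflammatory, vascular and metabolic programmes, and markers of brain cell types, blood cells and brain regions that a dissected hemisphere could hold. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists. The mean side difference of each list in single mice was compared between MCAO and sham mice by an exact two-sided permutation test over all 495 regroupings of the 12 mice. Named genes were the 10 with the greatest rise and the 10 with the greatest fall among probe sets past the threshold that had the same sign in every mouse of the group, or, between mice, groups that did not overlap. From each described list up to 4 called members with the greatest change were added, or the 2 with the smallest p where none passed, and a gene named in one comparison could be given in the others.

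The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. These alternatives were other treatments of the mouse block, only the mice of 1 surgery group, eBayes with trend and robust settings, leaving out dim probe sets, median centring, quantile normalization, array quality weights, only probe sets with 1 gene, the mean of all probe sets of a gene, and leaving out each mouse in turn. Leaving out the 4 arrays of MCAO mouse 3 and sham mouse 1 was added after seeing that they stood apart, and the naming rule was then applied to the remaining arrays as well. The signal of a named gene was taken as above background where it exceeded the 95th percentile of the negative control probe sets of its array, a criterion set after the results were seen. Where 0 arrays of the dimmer group passed it, a fold is given only as a lower bound, with each dim signal set to the higher of that percentile and its own value. The limma fits and the list tests were tested on simulated data with known changes. Noise was drawn independently for each probe set, so the simulation cannot show how the list tests behave when genes are correlated. With simulated log2 changes of 1 in 50 probe sets, limma recovered 80% in the within-mouse MCAO comparison on all arrays and 100% without the 4. It recovered 38% and 56% in the interaction, and 6% and 78% between the ipsilateral hemispheres of MCAO and sham mice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.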

Results

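RNA was measured on whole-transcript Affymetrix arrays in both hemispheres of 12 male C57Bl/6j mice aged 8 to 10 weeks. In 8 mice the middle cerebral artery was occluded on one side with an intraluminal filament for 90 min (middle cerebral artery occlusion, MCAO, a model of ischaemic stroke), followed by 30 min of reperfusion. The other 4 mice had sham surgery. Brains were taken 2 h after onset, and each hemisphere, ipsilateral or contralateral to the surgery, was hybridised to its own array, giving 24 arrays. The values were the log2 probe-set signals deposited by the authors, and 22206 probe sets that were not array controls were tested, of which 19572 named 1 gene. The number of arrays limits the precision of each value below.

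In 20 arrays the transcript profile was close to uniform, with a median Pearson correlation across probe sets to the others of 0.981 to 0.989. The 4 arrays of MCAO mouse 3 and sham mouse 1, both hemispheres of each, had correlations of 0.328 to 0.55 with those 20. Their signals were also compressed, with an SD over probe sets of 1.437 to 1.54 against 2.328 to 2.414 in the others. The mean of the positive control probe sets was 4.695 to 5.01 log2 units on these 4 arrays and 6.51 to 6.745 on the other 20. These arrays were kept in the main comparisons, and the main counts of called probe sets and lists are given again without them, a choice made after seeing the data.

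**Figure D1:**
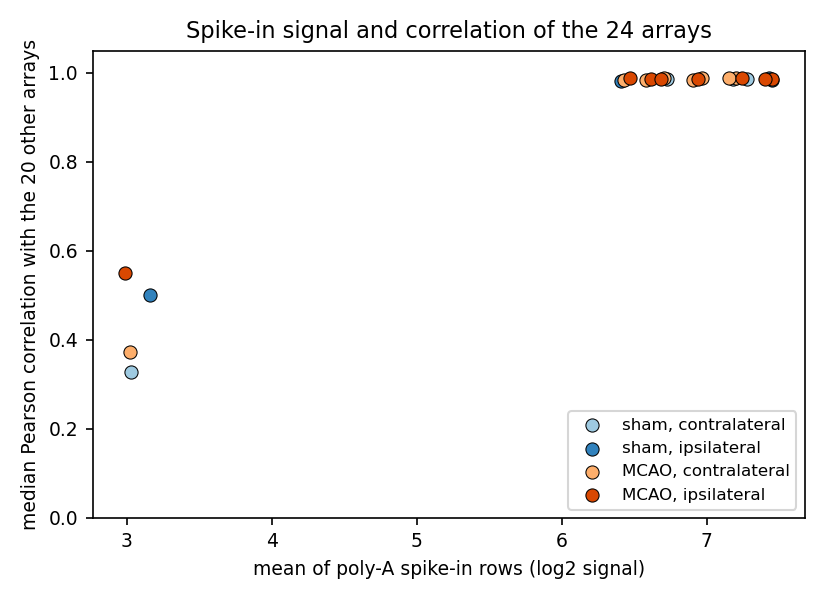
Quality measures of the 24 arrays, 1 point per array, coloured by group. The 4 arrays of MCAO mouse 3 and sham mouse 1 had median correlations of 0.328 to 0.55 with the other 20, which had 0.981 to 0.989 among themselves.

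The first comparison asked which transcripts differed between the occluded hemisphere and the opposite hemisphere of the same 8 mice. The chemokine gene Ccl3 (probe set TC1100003401.mm.2) was at least 1.55-fold higher on the occluded side (log2 difference 2.22 ± 0.25 SE, adjusted p = 0.0012, higher in 8 of 8 mice). This fold is a lower bound, since its contralateral signal was above background on 0 of 8 arrays. Ccn1 (TC0300003087.mm.2), which codes for a secreted matrix protein of the CCN family, was 3.53-fold higher (1.82 ± 0.21, adjusted p = 0.0012, 8 of 8 mice). Npas4 (TC1900000944.mm.2), an activity-dependent neuronal transcription factor, rose 5.15-fold (2.36 ± 0.41, adjusted p = 0.028) in 7 of 8 mice. Hspa1b, an inducible chaperone of the Hsp70 family, rose 2.83-fold (1.5 ± 0.25, adjusted p = 0.017, 8 of 8 mice). Npas4 and Hspa1b were above background on 5 and 2 of the 8 contralateral arrays. Hspa1a, a close copy of Hspa1b, was at 1.17 ± 0.31 with an adjusted p of 0.59, and probe sets of these near-identical genes can share signal.

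Among the 28 measured immediate early transcription factors, a class of genes transcribed within minutes of a stimulus, 10 rose over all probe sets tested and 18 when adjusted over the list alone, and 0 fell in limma. Fos rose 3.56-fold (1.83 ± 0.28, adjusted p = 0.0089, 7 of 8 mice) and Fosb 3.2-fold (1.68 ± 0.26, adjusted p = 0.0089, 7 of 8 mice). Atf3, a stress-induced factor, rose at least 1.44-fold (1.48 ± 0.21, adjusted p = 0.0062, 8 of 8 mice). Its contralateral signal was above background on 0 of 8 arrays. Egr4 and Nr4a1 were 2.59-fold and 2.4-fold higher, each in 8 of 8 mice. The list shifted upward with a median log2 difference of 0.63 (camera adjusted p = 1.04e-37). Of 26 activity-dependent neuronal effectors, 4 rose over all probe sets tested and 12 when adjusted over the list alone, among them Rgs2, a regulator of G protein signalling (1.64 ± 0.20), and Ptgs2, the inducible cyclooxygenase (1.63 ± 0.24). Gadd45g was at 1.32 ± 0.17 and Arc, a synaptic immediate early gene, at 1.07 ± 0.19, each higher in 8 of 8 mice with adjusted p-values of 0.0036 and 0.028. Dusp6, which dephosphorylates ERK, was the 1 member of 15 MAP kinase phosphatases and feedback inhibitors to rise over all probe sets tested (1.25 ± 0.19, adjusted p = 0.0089), against 5 when adjusted over the list alone. Of 21 genes of the vascular, protease and matrix response, Ccn1 and Thbs1 (0.99 ± 0.14, adjusted p = 0.0063, 8 of 8 mice), the gene of thrombospondin-1, rose over all probe sets tested, and 5 rose when adjusted over the list alone. Thbs1 was above background on 0 of 8 arrays of either side. Without the 4 arrays that stood apart, 12 immediate early factors were higher over all probe sets tested and 18 when adjusted over the list alone. The counts were then 6 and 17 for effectors, 2 and 9 for phosphatases and feedback inhibitors, and 2 and 7 for the vascular list.

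In all, 19 probe sets were higher and 0 lower on the occluded side in limma at an adjusted p under 0.05, with 918 at an unadjusted p under 0.05 where chance gives 1110. Without the 4 arrays that stood apart, 1577 probe sets had an unadjusted p under 0.05, above the number that chance gives. There 28 were higher and 2 lower at an adjusted p under 0.05, and 18 of the 19 were among them. Hspa1b was the exception, at 1.43 ± 0.28 with an adjusted p of 0.091. The 2 lower genes, Zfp189 at -0.66 ± 0.10 (adjusted p = 0.028, lower in 7 of 7 mice) and Cstad at -0.47 ± 0.08 (adjusted p = 0.049), were at -0.56 and -0.41 with adjusted p-values of 0.35 and 0.88 on all arrays. Cstad was above background on 0 of 7 arrays of either side. Other settings moved the count of 19, to 6 with quantile normalization, 9 with only the MCAO mice, 29 with mouse as a random block and 64 with array quality weights, of which 51 were higher and 13 lower. With the pairing of hemispheres within mice ignored, that is with no replicate block, limma gave 0 on all arrays and 29 on the 20. Leaving out MCAO mouse 8 left 10. Npas4 lost its call without MCAO mouse 1, 4, 5, 7 or 8 or sham mouse 1 or 2 (2.07 to 2.36, adjusted p = 0.051 to 0.16), and Arc without MCAO mouse 1, 2, 4, 5, 7 or 8 or sham mouse 2 or 4 (0.95 to 1.10, adjusted p = 0.05 to 0.16). Fos and Fosb lost theirs without MCAO mouse 1 or 8 (adjusted p = 0.05 to 0.052), Hspa1b without MCAO mouse 3, 4, 7 or 8 (1.3 to 1.43, adjusted p = 0.061 to 0.098), Nr4a1 without mouse 1, 4, 7 or 8 (1.13 to 1.26, adjusted p = 0.082 to 0.11) and Dusp6 without mouse 8 (1.18, adjusted p = 0.052).

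Over the 33 gene lists fixed before the data were examined, 15 shifted upward on the occluded side with camera, and 0 shifted downward. With an estimated correlation 4 calls held, those of immediate early transcription factors (adjusted p = 0.00164 with an estimated correlation), activity-dependent effectors (0.00483), MAP kinase phosphatases and the vascular list (both 0.0191). Without the 4 arrays that stood apart, the first 2 held (0.00805 and 0.0231), and the last 2 were at 0.0512. Camera then called 15 lists, 11 of them among those called on all arrays. Heat shock chaperones, which refold damaged proteins, shifted upward with a median of 0.23 over 19 genes (adjusted p = 6.11e-08, and adjusted p = 0.0662 with an estimated correlation), with 1 gene higher over all probe sets tested and 3 when adjusted over the list alone. NF-kB targets and adhesion molecules shifted by a median of 0.16 (adjusted p = 0.00351, and adjusted p = 0.231 with an estimated correlation), and 2 of 21 members rose when adjusted over the list alone. Zfp36, which codes for an mRNA-destabilising protein of that list, was at 1.10 ± 0.26 (adjusted p = 0.3). Striatal medium spiny neuron markers were positive in 17 of 17 genes with a median of 0.17 (adjusted p = 0.000275, and adjusted p = 0.254 with an estimated correlation). Upward shifts were also called for sterol biosynthesis (median 0.17, adjusted p = 0.183 with an estimated correlation), potassium channels and pumps (0.12, adjusted p = 0.293 with an estimated correlation), circadian clock genes (0.15, adjusted p = 0.183 with an estimated correlation) and the unfolded protein response (0.06, adjusted p = 0.234 with an estimated correlation). The same held for oxidative phosphorylation subunits (0.17, adjusted p = 0.441 with an estimated correlation), cytosolic ribosomal proteins (0.12, adjusted p = 0.421 with an estimated correlation), pan-neuronal markers (0.15, adjusted p = 0.492 with an estimated correlation) and astrocyte markers (0.09, adjusted p = 0.377 with an estimated correlation). MCAO mouse 3, whose arrays stood apart, had a mean side difference of 0.79 in the pan-neuronal and 0.94 in the oxidative phosphorylation list, against 0.08 and 0.16 in the next highest mouse, and without this mouse 9 of the 15 calls held. The 6 that ended were those of circadian, astrocyte, pan-neuronal, potassium, oxidative phosphorylation and ribosomal genes, with means of 0.03 to 0.08 (adjusted p = 0.0979 to 0.367). The unfolded protein call ended without MCAO mouse 4, 7 or 8 (mean 0.09 to 0.1, adjusted p = 0.0737 to 0.122), the astrocyte call also without mouse 2, 4, 5 or 8 (0.1 to 0.12, adjusted p = 0.0576 to 0.0937) and the ribosomal call also without mouse 5 (0.12, adjusted p = 0.0501).

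The other 18 lists did not pass camera on the occluded side against the other on all arrays, to which the values of this paragraph belong. Without the 4 arrays that stood apart, 15 lists were called and 11 of these were among the lists called on all arrays. Some of the 18 were therefore called there, though with an estimated correlation only the immediate early and effector lists passed. Cytokines and chemokines, in which Ccl3 was the 1 gene of 24 to rise, had a median of 0.08 (adjusted p = 0.0697). Most of its members were dim, and 3 had a mean signal at or above the median of all probe sets. The mean side difference of these 3 was 0.79 ± 0.33 (SD) in MCAO mice, positive in 8 of 8. In the 4 sham mice it was 0.05 ± 0.22 (SD, exact permutation p = 0.00404, adjusted p = 0.0626). The list median is thus no evidence that its detectable members were unchanged. Hypoxia and HIF-1 targets had a median of 0.11 over 26 genes with 0 called in either direction (adjusted p = 0.0697), and the prolyl hydroxylase subunit gene P4ha1 was at 0.64 ± 0.17, higher in 8 of 8 mice, with an adjusted p of 0.64. Markers of oligodendrocytes (adjusted p = 0.0645), microglia (0.297), endothelium (0.69), pericytes and smooth muscle (0.53), choroid plexus and ependyma (0.36), reactive astrocytes (0.661), neutrophils and monocytes (0.8) and erythroid cells (0.233) were not called. Neither were p53 targets (0.315), oxidative stress genes (0.156), glucocorticoid-responsive genes (0.284), interferon-stimulated genes (0.85), glutamate and GABA receptor subunits (0.156), or the hypothalamic (0.401), cerebellar (0.981) and olfactory or thalamic (0.0961) lists.

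**Figure D2:**
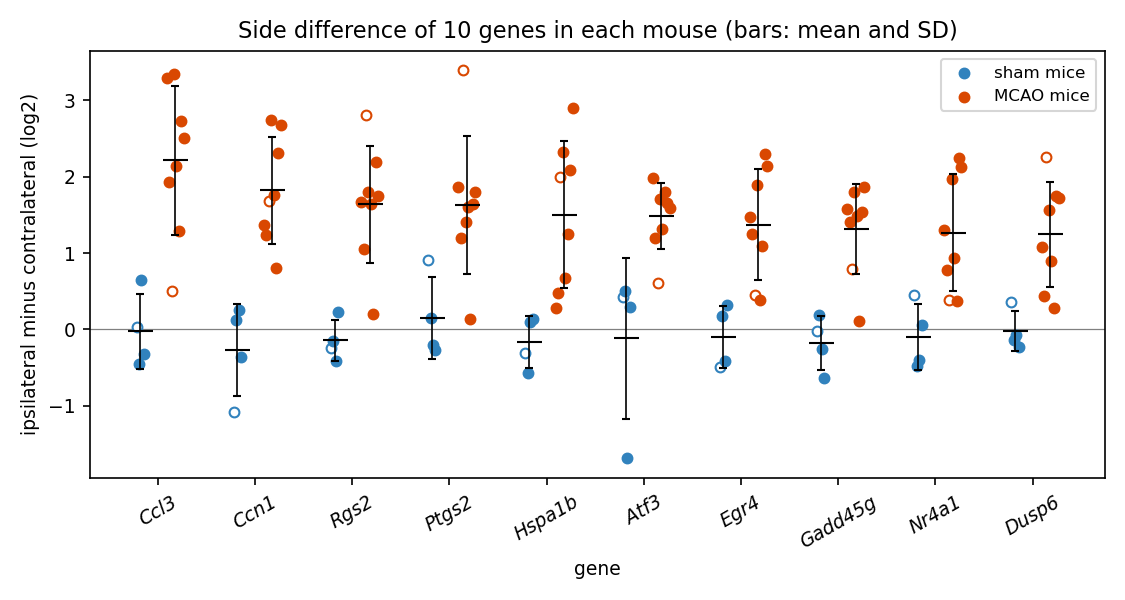
Ipsilateral minus contralateral log2 difference of single mice for named genes, with bars for the mean and SD of all mice of a surgery group and open circles for MCAO mouse 3 and sham mouse 1. The mean over the list of immediate early transcription factors, which is not drawn, was above 0 in 8 of 8 MCAO mice, at 0.76 ± 0.32 (SD). It was -0.02 ± 0.06 (SD) in the 4 sham mice.

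The hemispheres of the 4 sham mice gave the background of the side comparison. Ccl3 differed by -0.03 ± 0.36 between the sides of sham brains, Ccn1 by -0.27 ± 0.29, Npas4 by -0.44 ± 0.58 and Hspa1b by -0.16 ± 0.35, and Ccl3, Ccn1 and Hspa1b were each higher on the operated side in 2 of 4 mice. Arc was at 0.42 ± 0.26 and higher in 4 of 4 mice. In limma 0 probe sets passed, with 1390 at an unadjusted p under 0.05 and a smallest adjusted p of 0.263. On the 20 other arrays 0 passed as well, with 1220 at an unadjusted p under 0.05. Pan-neuronal markers (median 0.31, adjusted p = 0.00195), oxidative phosphorylation subunits (0.31, adjusted p = 0.000221), striatal markers (0.30, adjusted p = 0.0024) and astrocyte markers (0.23, adjusted p = 0.0404) shifted upward on the operated side with camera, and each had an adjusted p of 0.887 with an estimated correlation. Sham mouse 1, whose arrays stood apart, had side differences of 1.34 in the pan-neuronal and 1.45 in the oxidative phosphorylation list, against 0.11 and 0.1 in the next highest sham mouse. On the 20 other arrays these shifts were not called, and 1 list passed, the oligodendrocyte markers with a median of -0.15 (adjusted p = 0.0363, and adjusted p = 0.939 with an estimated correlation). Leaving out sham mouse 3 gave 1 called probe set, and leaving out sham mouse 1 left 0 of the 4 list shifts. The astrocyte shift was also lost without sham mouse 4 (mean 0.21, adjusted p = 0.0894).

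Whether the side difference was greater after occlusion than after sham surgery was tested as the interaction of side and surgery. The difference between the side differences was 2.24 ± 0.44 for Ccl3, 2.09 ± 0.36 for Ccn1, 1.78 ± 0.35 for Rgs2 and 2.80 ± 0.71 for Npas4, with adjusted p-values of 0.52, 0.45, 0.52 and 0.89. In limma 0 probe sets passed, with 1138 at an unadjusted p under 0.05, and without the 4 arrays that stood apart 0 passed with 1312. With mouse as a random block 1 passed. As a list, the immediate early transcription factors passed, with a median interaction of 0.64 (camera adjusted p = 8.36e-16, adjusted p = 0.0466 with an estimated correlation), 0 members over all probe sets tested and 15 higher when adjusted over the list alone. That call was at an adjusted p = 0.0714 with an estimated correlation without the 4 arrays. Activity-dependent effectors (adjusted p = 5.06e-06, and adjusted p = 0.352 with an estimated correlation) and MAP kinase phosphatases (adjusted p = 9.52e-05, and adjusted p = 0.3 with an estimated correlation) also shifted upward. NF-kB targets and the vascular list each had an adjusted p of 0.0384, with 0.587 and 0.364 as the adjusted p with an estimated correlation. The mean NF-kB interaction of 0.24 was 0.09 without sham mouse 1 (adjusted p = 0.409). That mouse had a side difference of -0.56, against 0.03 to 0.16 in the other sham mice. The call also ended without MCAO mouse 2, 4 or 7. The vascular call ended without MCAO mouse 2, 4, 7 or 8 or sham mouse 2, 3 or 4 (mean 0.24 to 0.29, adjusted p = 0.0639 to 0.112). Leaving out mice gave 3 to 8 lists in place of these 5, with 3 without MCAO mouse 2, 4 or 7 and 8 without MCAO mouse 3 or sham mouse 1. Without the 4 arrays 7 were called, with NF-kB targets not among them (adjusted p = 0.414).

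All errors after a mean in this paragraph are SDs over mice. In single mice, the mean over the immediate early transcription factors was 0.76 ± 0.32 (SD, n = 8) higher on the occluded side and -0.02 ± 0.06 (SD, n = 4) in sham mice. The difference of 0.78 had an exact two-sided permutation p of 0.00404 over 495 regroupings, where 0.00202 is the smallest possible. MAP kinase phosphatases were at 0.37 ± 0.24 in MCAO mice and -0.05 ± 0.12 in sham mice (exact permutation p = 0.0101), and the vascular list at 0.27 ± 0.16 and 0.00 ± 0.09 (exact permutation p = 0.0101). These 3 lists had an adjusted p of 0.111 over the 33 lists. Olfactory bulb and thalamic genes, a list of region markers, were at 0.08 ± 0.15 and -0.11 ± 0.04 (exact permutation p = 0.0323, adjusted p = 0.267). At the smallest possible p a single list could not pass that adjustment, whatever its difference, so the count of 0 that passed says little. Heat shock chaperones were higher on the occluded side in 8 of 8 MCAO mice, at 0.34 ± 0.25, against 0.17 ± 0.32 in sham mice (exact permutation p = 0.36). Sham mouse 1 was at 0.65 and the other sham mice at -0.08 to 0.1. Without the mice that stood apart, the immediate early list was at 0.83 ± 0.28 in 7 MCAO mice and -0.02 ± 0.07 in 3 sham mice, with an exact permutation p of 0.00833, the smallest possible, and an adjusted p of 0.138. Activity-dependent effectors were then at 0.54 ± 0.24 and -0.02 ± 0.11 (exact permutation p = 0.00833), against an exact permutation p of 0.0485 with all mice. Heat shock chaperones were at 0.26 ± 0.14 and 0.02 ± 0.09 (exact permutation p = 0.0417), and MAP kinase phosphatases at 0.39 ± 0.25 and -0.02 ± 0.12 (exact permutation p = 0.0417). The vascular list was at 0.29 ± 0.16 and 0.05 ± 0.04 (exact permutation p = 0.05). Each of these 3 had an adjusted p of 0.241, as had p53 targets, at 0.07 ± 0.06 and -0.05 ± 0.08 (exact permutation p = 0.025).

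**Figure D3:**
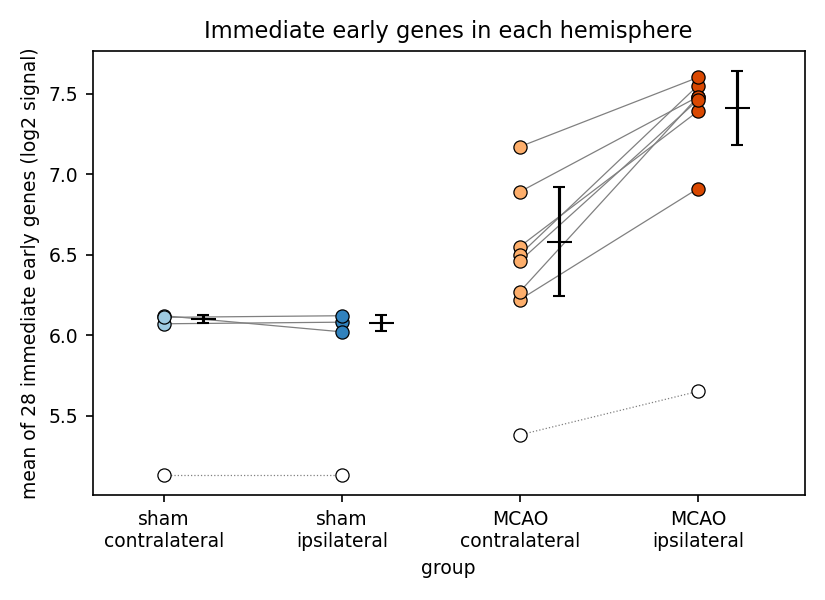
Mean log2 signal of the 28 immediate early transcription factors on each array by group, with open circles for MCAO mouse 3 and sham mouse 1 and bars for the mean and SD without these mice. The means were 7.41 ± 0.23 in the occluded and 6.58 ± 0.34 in the contralateral hemispheres of MCAO mice (n = 7), and 6.07 ± 0.05 and 6.10 ± 0.03 in the ipsilateral and contralateral hemispheres of sham mice (n = 3).

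The occluded hemisphere was also compared with the ipsilateral hemisphere of sham mice, that is between animals. Ccn1 was 9.85-fold higher after occlusion, at 9.24 ± 0.68 log2 units (SD, n = 8) against 5.94 ± 0.37 (SD, n = 4), a log2 difference of 3.30 ± 0.36 (SE, adjusted p = 0.013), and the groups did not overlap. It was the 1 probe set that passed in limma, with 225 at an unadjusted p under 0.05. Npas4 was at 4.42 ± 0.76 (adjusted p = 0.34), Fos at 3.09 ± 0.62 (adjusted p = 0.65) and Ccl3 at 2.57 ± 0.47 (adjusted p = 0.37) on all arrays. The Ccn1 call ended when MCAO mouse 1, 2, 5 or 8 or any 1 of the 4 sham mice was left out, and with mouse number as a replicate block, each giving 0. Over those mice its difference was 3.12 to 3.38 with an adjusted p of 0.051 to 0.091. Leaving out MCAO mouse 3 gave 17, and array quality weights gave 50, of which 42 were higher and 8 lower.

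Without the 4 arrays that stood apart, 28 probe sets were higher and 5 lower in the occluded hemisphere than in the sham hemisphere, 7 mice against 3, and the naming rule was applied to these in the same way. An unadjusted p under 0.05 was then found for 1661 probe sets, where chance gives 1110. Npas4 was at least 16.4-fold higher (4.88 ± 0.22, adjusted p = 2.3e-08), with sham signal above background on 0 of 3 arrays. Ccn1 was 10.2-fold higher (3.34 ± 0.15, adjusted p = 2.3e-08). Fos (3.23 ± 0.21, adjusted p = 2.5e-06), Ccl3 (3.18 ± 0.30, adjusted p = 9.5e-05), Fosb (2.57 ± 0.24) and Nr4a1 (2.43 ± 0.23) followed, and in each of these the groups did not overlap. Among effectors and feedback genes, Ptgs2 was at 2.10 ± 0.22, Gadd45g at 1.97 ± 0.16, Rgs2 at 1.88 ± 0.22, Dusp6 at 1.80 ± 0.13 and Dusp1 at 1.69 ± 0.12, with adjusted p-values from 4.7e-06 to 0.00066. In the vascular list 4 of 21 genes rose over all probe sets tested and 6 when adjusted over the list alone, including the metalloprotease gene Adamts1 (1.90 ± 0.23, adjusted p = 0.0011) and the endothelial gene Apold1 (1.77 ± 0.21, adjusted p = 0.00066). Ccl3, Adamts1 and Apold1 were above background on 0 of 3 sham arrays, which makes them at least 1.99-fold, 2.66-fold and 2.36-fold higher. Ciart, a circadian repressor, was 2.18-fold higher (1.12 ± 0.17, adjusted p = 0.013). Cebpb was at 0.80 ± 0.14 (adjusted p = 0.025) and above background on 1 of 7 occluded and 0 of 3 sham arrays. The 5 probe sets with lower values were not above background on any of these arrays of either group, so their differences are no measure of a fold. They were Slc16a9, a member of the monocarboxylate transporter family (-0.94 ± 0.14, adjusted p = 0.013), the transcription factor gene Gata2 (-0.93 ± 0.15, adjusted p = 0.024), the collagen gene Col23a1 (-0.82 ± 0.14, adjusted p = 0.024), Zfp648 (-0.92 ± 0.16) and 5830454E08Rik (-0.97 ± 0.16). On all arrays these 5 had an adjusted p of 0.97.

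In this comparison with all arrays, 21 lists were called by camera, 19 upward and 2 downward, and 2 held with an estimated correlation. Leaving out sham mouse 1 turned the direction of 11 of the 21, of which 5 were then called the other way, and left 5 called in their first direction. The 2 that held were the immediate early transcription factors (median 1.16, adjusted p = 0.0346 with an estimated correlation, 17 of 28 higher when adjusted over the list alone and 0 over all probe sets tested) and the vascular list (median 0.19, adjusted p = 0.0346 with an estimated correlation). Leaving out the 4 arrays, 13 lists were called and 3 held with an estimated correlation, with the vascular list not among these 3. The immediate early list then had 11 genes higher over all probe sets tested and 21 when adjusted over the list alone (adjusted p = 0.00655 with an estimated correlation). Activity-dependent effectors had 6 and 17 of 26 (adjusted p = 0.00655 with an estimated correlation), and MAP kinase phosphatases had 2 and 7 of 15 (adjusted p = 0.0247 with an estimated correlation). Heat shock chaperones had 0 genes over all probe sets tested and 4 when adjusted over the list alone (adjusted p = 1.93e-06, and adjusted p = 0.0973 with an estimated correlation), with the small heat shock protein gene Hspb1, not above background in either group, at 0.76 ± 0.15 (adjusted p = 0.086) and Hspa1b at 1.5 ± 0.40 (adjusted p = 0.3).

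Contralateral hemispheres were compared between MCAO and sham mice to ask whether the side without occlusion differed. Apold1 was 0.94 ± 0.21 log2 units higher in the contralateral hemisphere of MCAO mice on all arrays and 1.04 ± 0.15 without the 4 arrays, with adjusted p-values of 1 and 0.17. Without those arrays the groups did not overlap. Since the sham signal was above background on 0 of 3 arrays, only a lower bound of 1.3-fold can be given for the group means. This bound holds no sampling error, and the gene was not called. Ccn1 was at 1.21 ± 0.47 with all arrays (7.42 ± 0.93 SD, n = 8, against 6.20 ± 0.35 SD, n = 4) and 1.51 ± 0.38 without the 4. Npas4 was at 1.62 and 1.83 ± 0.75, Fos at 1.42 and 1.20 ± 0.49, and Btg2, an antiproliferative immediate early gene, at 1.11 ± 0.33 and 1.00 ± 0.29. The chaperone Hspa1b was at -0.17 ± 0.29 and -0.04, and Ccl3 at 0.33 ± 0.41 and 0.67 ± 0.31. The contralateral Ccl3 signal of MCAO mice was not above background on any array, so its difference is no measure of a fold. In limma 0 probe sets passed, with 81 at an unadjusted p under 0.05 on all arrays and 1020 without the 4, and with array quality weights 1 passed. Immediate early transcription factors shifted upward with camera, with a median of 0.56 and 26 of 28 genes positive (adjusted p = 2.05e-13, and adjusted p = 0.32 with an estimated correlation), and 1 gene rose when adjusted over the list alone. On the 20 other arrays the median was 0.41 (adjusted p = 1.67e-12, and adjusted p = 0.402 with an estimated correlation), and 3 genes rose when adjusted over the list alone. Camera called 15 lists on all arrays and 6 without the 4 arrays, and with an estimated correlation 0 of either. Pan-neuronal markers and oxidative phosphorylation subunits had medians of 0.47 and 0.48 on all arrays (adjusted p = 0.826 with an estimated correlation for each) and of 0.02 each without the 4. Leaving out sham mouse 1 turned the direction of 11 of the 15 lists, 7 of them then called the other way, with mean differences of -0.33 and -0.38 for these 2 lists.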

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

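The 3 tests of why 4 arrays stood apart, the test of unequal array quality between the sides, the test of spilled tissue and all values without the 4 arrays were chosen only after the results were seen. Of 54 groups of 4 to 10 values examined, 23 held a value far from the others, where chance sets about 1 in 20 groups apart in this way.

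MCAO mouse 3 and sham mouse 1 stood far from the other mice in both hemispheres: in the contralateral and ipsilateral array of MCAO mouse 3, the SD of log2 signal was 1.475 and 1.54, the median Spearman correlation with the 20 other arrays 0.379 and 0.54, the area under the curve separating positive from negative control probe sets 0.654 and 0.7, and the mean of the poly-A spike controls 3.024 and 2.989. In sham mouse 1 the SD was 1.437 and 1.536, the correlation 0.335 and 0.494 and the area under the curve 0.646 and 0.694, and the poly-A spikes were at 3.03 on the contralateral array. The surgery as the cause is argued against, since 1 mouse of each surgery group stood apart and 10 of the 12 mice did not, and another tissue in the tube as the whole cause is argued against, since the positive control probe sets lay below all 20 other arrays on 4 of 4, but the 4 arrays correlated at 0.74 to 0.81 with each other, so a profile of another tissue beside too little target was not excluded. Too little amplified target remains open as a candidate explanation, since on 4 of 4 arrays the poly-A spikes, added before amplification, lay below all 20 others and the BioB hybridization spike, added after it, lay above all 20 (10.16 to 10.42 against 6.224 to 8.469). No biological explanation other than the surgery was tested, and degraded RNA, which the spikes would not show, was not tested.

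Pan-neuronal markers and oxidative phosphorylation subunits were far higher on the ipsilateral side in the same mice. The pan-neuronal side difference was 0.79 in MCAO mouse 3 (next mouse 0.08) and 1.34 in sham mouse 1 (next mouse 0.11), and that of oxidative phosphorylation subunits was 0.94 (0.16) and 1.45 (0.1). A side difference of the brain or dissection common to all mice is argued against, since both lists were positive in 5 of the 10 remaining mice, but an uneven dissection in these 2 mice alone was not tested. Unequal array quality of the 2 sides in the mice standing apart may account for it and stays open, since in 2 of 2 the ipsilateral array separated positive from negative controls better (0.7 against 0.654, and 0.694 against 0.646), which 2 mice are too few to decide.

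Immediate early transcription factors were 0.48 log2 units higher in the contralateral hemispheres of 7 MCAO mice than of 3 sham mice without the apart mice, although no estimated-correlation test called the list. For this list taken alone, chance among few sham mice is argued against by the exact one-sided permutation p of 0.0083, 1 of 120 splits and the smallest possible. The exact two-sided p was 0.042, and neither was adjusted over the 33 lists. Array quality stays open, since with the control separation as a covariate 86% of the difference remained (0.42 ± 0.23 SE). Tissue of the occluded side in the contralateral piece also stays open. Over 28 genes called on the ipsilateral side the contralateral excess was a median 18.9% of the ipsilateral excess, with medians of 6.8% to 69.8% in single mice. Medians of genes ran from 1.5% for Rgs2 to 82.9% for Maff (not above background). These shares differed between genes (permutation p = 1e-04, the smallest the permutations can give, and p = 0.008 against redrawn noise with 1 share per mouse). The permutation ignores that the shares of all mice rest on the same sham levels. The redrawn noise allows for this, but takes its spread from 3 sham mice and gives the ipsilateral values of MCAO mice no noise. Both tests used genes chosen by their ipsilateral rise over sham in the same arrays that form the denominator of each share. Some of these genes, among them Ccl3, Adamts1, Apold1 and Cebpb, were not above background on any remaining ipsilateral sham array. Unequal shares would go against spilled tissue with the profile of the whole occluded hemisphere, but these limits leave that undecided. Also, 0 genes exceeded the ipsilateral excess in every mouse. Unequal shares were written down as the result that would exclude spilled tissue, and this was judged too strict after that result was seen, because spilled tissue need not have that profile and another profile was not tested, so a response of the contralateral hemisphere itself and spilled tissue cannot be told apart.

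Other values that stood far from their group were the immediate early side difference of sham mouse 3, -0.1 with the next mouse at 0, and its Atf3 side difference, -1.69 with the next at 0.3. The log2 signal of Ccn1 was 7.646 in the occluded hemisphere of MCAO mouse 3 (next 9.098) and 5.386 in the ipsilateral hemisphere of sham mouse 1 (next 6.082).

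The side difference differed between MCAO and sham mice for 5 lists by the camera test of the interaction. The mean difference was 0.78 for immediate early transcription factors, 0.4 for activity-dependent effectors, 0.42 for MAP kinase phosphatases, 0.24 for NF-kB targets and 0.27 for the vascular list, and with an estimated correlation the first held on all arrays (adjusted p = 0.0466) and was lost without the 4 arrays (adjusted p = 0.0714). The NF-kB value rests on sham mouse 1, whose arrays stood apart: without it the mean difference was 0.09 (adjusted p = 0.409), and without both apart mice 0.11.

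Counts of calls were compared with those of other splits of the same mice. For probe sets in MCAO mice, with sides exchanged within mice, 1 of 100 splits gave as many as the real 19 (highest other 4), and without the 4 arrays 1 of 64 gave as many as 30 (highest other 2). In both, the 1 split was the real one, so chance is argued against at 0.05, without adjustment for the number of split tests. For the lists in that comparison 3 of 100 splits gave as many as 15 (highest other 15), and without the 4 arrays 3 of 64 (real 15, highest other 16). These shares lie under 0.05, but other splits reached the real count and the tests of splits were not adjusted for their number. Chance is therefore not firmly excluded for these lists. Between ipsilateral hemispheres 1 of 100 splits gave as many probe sets as the real 1 (highest other 0), and 1 of 100 without the 4 arrays (real 33, highest other 2). Chance is argued against there at 0.05, again without adjustment for the number of split tests. The real 1 is the Ccn1 call, which ended when single mice were left out, so the result on all arrays is not firm. For the lists there, 38 of 100 gave as many as 21 (highest other 26) and, without the 4 arrays, 7 of 100 as many as 13 (highest other 16), so chance is not excluded. Chance is not excluded either for the lists of the interaction, where 38 of 100 splits gave as many as 5 (highest other 15), or for those between contralateral hemispheres, with 71 of 100 as many as 15 (highest other 26) and, without the 4 arrays, 46 of 100 as many as 6 (highest other 14). For probe sets these comparisons had a real count of 0, which 100 of 100 splits reach whatever the data, so the splits tell nothing there (highest other 1 in the interaction, 0 between contralateral hemispheres and 2 there without the 4 arrays). The sham side comparison has 8 splits, too few for a share under 0.05, with 8 of 8 for probe sets (real 0, which any split reaches, highest other 0) and 5 of 8 for lists (real 4, highest other 8).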

How the results depend on the processing

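All settings without the 4 arrays that stood apart were chosen after the results were seen, as was the choice to follow in the comparisons between mice only the lists the text describes; the others were planned. Numbers of called probe sets moved as follows, and the cause was not tested unless given. For the 19 of the MCAO side comparison, no replicate block gave 0, mouse as a random replicate block 29, only the MCAO mice 9 (fewer arrays), quantile normalization 6, array quality weights 64 (51 higher, 13 lower), leaving out 1 mouse 10 (without MCAO mouse 8) to 23, and leaving out the 4 arrays 30, or 29 with no replicate block. On those 20 arrays, leaving out a further mouse gave 18 to 27. For the 0 of the sham comparison, leaving out 1 mouse gave 0 to 1, and for the 0 of the interaction the random replicate block gave 1. For the 1 between ipsilateral hemispheres, mouse number as a replicate block gave 0, array quality weights 50 (42 higher, 8 lower), leaving out 1 mouse 0 to 17 (without MCAO mouse 3) and leaving out the 4 arrays 33, then 24 to 46 without a further mouse. For the 0 between contralateral hemispheres array quality weights gave 1. The replicate block changed no other count by over 1.5 times, except that the 4 list shifts of the sham comparison became 2 with no replicate block. Numbers of called lists with an estimated correlation, and with fry, were 4 and 5 of 15 (MCAO side), 0 and 0 of 4 (sham), 1 and 1 of 5 (interaction), 2 and 1 of 21 (ipsilateral) and 0 and 0 of 15 (contralateral). Without the 4 arrays the numbers were 1 (sham, downward), 13 (ipsilateral) and 6 (contralateral), and with an estimated correlation 2, 0, 0, 3 and 0 in the same order of 5 comparisons. Leaving out 1 mouse gave 0 to 5 lists (0 without sham mouse 1) in the sham comparison and 3 to 8 in the interaction. Leaving out sham mouse 1 turned camera's direction in 11 of 21 ipsilateral lists, 5 of them then called, and in 11 of 15 contralateral lists, 7 of them then called. Over the mice left out, the mean ranged from -0.22 to 0.55 for pan-neuronal markers and -0.21 to 0.6 for oxidative phosphorylation between ipsilateral hemispheres. Between contralateral hemispheres it ranged from -0.33 to 0.87, and -0.38 to 0.9 for these lists, -0.21 to 0.7 for heat shock chaperones, -0.13 to 0.7 for sterol biosynthesis and -0.05 to 0.77 for activity-dependent effectors (only the mean turned, not camera's direction), each lowest without sham mouse 1. Leaving out the 4 arrays turned 1 ipsilateral and 2 contralateral lists. Of 365 values of named genes, 291 kept direction and call, 74 kept direction and lost the call and 0 reversed. Of 704 values of lists, 533 kept both, 164 lost the call and 7 reversed, and 20 of 20 values of lists in single mice kept direction. Low signal over background limits the 4 arrays, whose area under the curve of positive over negative controls was 0.646 to 0.7 against 0.896 to 0.932.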

Other observations

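The values without the 4 arrays that stood apart were chosen only after the results were seen. Sterol biosynthesis genes, which make cholesterol from acetyl-CoA, shifted upward between the ipsilateral hemispheres of MCAO and sham mice, with a median of 0.53 on all arrays and 0.37 without the 4 arrays (camera adjusted p = 1.96e-05 and 6.89e-08, adjusted p = 0.678 and 0.0828 with an estimated correlation). Leaving out sham mouse 1 alone ended the call, with a mean of 0.09 (adjusted p = 0.236). Over all probe sets tested 0 of the 16 genes passed in limma, and without the 4 arrays 5 were higher when adjusted over the list alone. Stard4, a cholesterol carrier above background on 0 of 3 sham arrays, was at 0.76 ± 0.17 and Idi1, an isomerase of the mevalonate pathway, at 0.72 ± 0.17 without the 4 arrays, each with an adjusted p of 0.19 and groups that did not overlap. On the occluded side against the other, Idi1 was at 0.47 ± 0.14 on all arrays and higher in 8 of 8 mice (adjusted p = 0.92).

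Striatal medium spiny neuron markers, genes of the main neurons of the striatum, were called upward on the occluded side within MCAO mice (adjusted p = 0.254 with an estimated correlation) and downward between MCAO and sham mice without the 4 arrays. The mean side difference was 0.23 in MCAO and 0.36 in sham mice (exact permutation p = 0.626), and 0.14 and 0.09 without the apart mice (exact permutation p = 0.783). Between mice without the 4 arrays, the median was -0.19 for ipsilateral hemispheres (adjusted p = 0.0364, and adjusted p = 0.722 with an estimated correlation), with 2 of 17 genes positive. It was -0.19 for contralateral hemispheres as well (adjusted p = 0.0219, and adjusted p = 0.779 with an estimated correlation), with 1 of 17 positive. Tac1, which codes for the neuropeptide substance P, was higher on the occluded side in 8 of 8 mice (0.66 ± 0.27, adjusted p = 0.94).

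The hypothesis that mice with a stronger immediate early response also had a stronger heat shock response, as 1 common strength per mouse, was tested over the 7 MCAO mice without mouse 3. Spearman's rho between the 2 list side differences was 0.29 (exact permutation p = 0.53) and Pearson's r was 0.31 (exact permutation p = 0.5), with 0.66 after leaving out the 2 mice farthest from the median. This was the 1 relation tested, and 7 mice leave it undecided.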
